A study of Danio rerio with 2 samples.

How the data were processed

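The data were droplet-based single-cell RNA counts of polyadenylated RNA from adult zebrafish meninges, prepared with 10x Genomics 3.1 kits per the labels. There were 2 samples, leptomeninges and pachymeninges, each pooled from several fish and deposited as 4 and 6 matrices, called libraries here. The deposited values are filtered matrices of raw UMI counts per gene and barcode, made with Cell Ranger 7.0.0 per the submitters' processing notes. The genome build and gene annotation are not given in the sources used here. Features carry Ensembl identifiers and symbols, and 5 reporter sequences were listed in some or all libraries. The 3 versions of the feature list differ in these reporters, so 32520 genes were common to all libraries, and the feature list was treated as a possible batch. The symbols of 4094 features are shared by more than 1 identifier. These were counted by identifier and left out of the counts and medians of gene lists between tissues and across classes, and genes with near-identical copies are uncertain.

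Each library was filtered alone. Barcodes with fewer than 200 genes or with more than 20% of UMIs from mitochondrial protein genes were removed. Mitochondrial ribosomal and transfer RNAs were left out of that share after the data were seen, because the median share of leptomeningeal library C2 was 22.1% without and 34.8% with them. Barcodes were ranked by Scrublet score (scanpy 1.11.5) within each library, and the top 0.8% per 1000 barcodes of the library were removed as doublets, so their number follows from the rate and not from a score threshold. These were 2833 leptomeningeal and 306 pachymeningeal barcodes, 3.72% to 9.32% of barcodes in the leptomeningeal libraries and 0.758% to 2.70% in the pachymeningeal ones. Kept cells held 43919669 leptomeningeal and 27689263 pachymeningeal UMIs. Between libraries of a tissue Pearson's r of log CPM across genes was 0.981 to 0.996 for the 6 leptomeningeal and 0.907 to 0.975 for the 15 pachymeningeal pairs, where genes are not independent replicates. At most 0.387% and 0.388% of barcodes were shared, and chi-square per degree of freedom was at least 6.06 and 6.62, so no library repeated another.

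For clustering, counts were scaled to 10000 per cell and log-transformed, and 2000 genes variable across libraries were taken after all members of the 12 gene lists were left out. Values were scaled and clipped at 10, 40 principal components and 20 neighbours were used, and Leiden clustering ran at resolution 1.0 with seed 7, over all libraries together and without batch integration. The 41 clusters were named from 28 marker lists fixed before the data were examined. The naming thresholds were set after the data were seen: each list was scored by its mean log2 level over the lower quartile of clusters with an offset of 5 CPM, and a marker counted as detected in over 10% of the cluster's cells and at over 4 times that quartile. The list with the highest score gave the name where at least 3 of its markers were detected and where either 1 of them was among the cluster's top 10 genes by fold or the score led the next list by at least 2. A cluster whose median depth times 3 was below its tissue's median stayed without a name unless such a marker was among its top 10 genes. This left 7 clusters without a name and 17 named classes, called X-like in the text. The macrophage or microglia class was named from the microglia list. The share among remaining cells was added after the shares were seen. The 3 genes with the largest ratio over all other cells define a class and are no results, and where fewer are given the remaining one is not reported here: igic1s1, igl3v5 and igl1c3 for B cell-like, il4, ccl34b.3 and il13 for NK or innate lymphoid-like, ccl38a.5, traj60 and prf1.1 for T cell-like, slc2a1a, flt1 and cxcl12b for blood endothelial-like, icn2 and tmprss13b for epithelial or keratinocyte-like, slc4a1a, nt5c2l1 and epb41b for erythroid-like, lum, cyp1c2 and ifitm1 for fibroblast-like, apoda.1, lypc and defbl1 for iridophore-like, slc22a7b.1, cp and epd for barrier-like, cmklr1, cx32.2 and havcr1 for macrophage or microglia-like, ndufa4l2a and rasl12 for mural-like, sst1.1, pyya and ucn3l for neuron-like, lyz, scpp8 and mmp9 for neutrophil-like, crp1, mpz and cd59 for oligodendrocyte or Schwann-like, gpc5b, slc1a2b and hspb15 for radial glia or astroglia-like, lyve1b, mrc1a and angpt2a for lymphatic endothelial-type scavenger and itga2b, mpl and thbs1b for thrombocyte-like cells. Some of these are also members of gene lists or named genes, where they are given as values of the tissues.

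The comparisons, the rule of size, the gene and marker lists and the rule for named genes were fixed before the data were examined. With 1 sample per tissue no test across samples was possible, so no p-value is given. UMI counts of kept cells were summed over the libraries of a tissue and divided by their total to give CPM. A gene counted as higher in a tissue at 20 CPM or more, a ratio of at least 2 and every library of that tissue above every library of the other. Ratios have exact conditional binomial intervals and shares exact Clopper-Pearson intervals at the 95% level, which cover counting error only. A ratio against a count of 0 was taken against a floor of 3 counts over the tissue. Within a class, at least 100 cells per tissue were asked for, libraries with at least 20 cells of the class entered the library range, and the class CPM had to reach that of the whole sample, which guards against free RNA only as far as that has the composition of the whole sample. Neuron-like cells were not compared between tissues, because clusters 2 and 28 had a marker of another class (gata2a and eomesa) and none of their own among their top 10 genes, and no single neuron-like cluster had 100 cells in both tissues. As a class, with 17920 and 251 cells, they met the fixed minimum. The grounds for leaving them out were not part of the comparisons fixed in advance. This left T cell-like and erythroid-like cells. The named genes were the 12 of the whole samples and the 8 of each class with the largest ratios in each direction, without mitochondrial, haemoglobin and clone-named genes (names with zmp: and all other clone names were added to the fixed exclusions after the data were seen), up to 4 members of each gene list with the highest CPM among those that met the rule, and the reporters. For each of the 12 gene lists (333 members) the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries. Members that are also markers were left out of list counts between classes.

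To test for a single pool of free RNA, leptomeningeal barcodes with a UMI of a GABA gene (gad1a, gad1b, gad2 or slc32a1) and of a glutamate gene (slc17a6a, slc17a6b or slc17a7a) were counted against independence within each library, with an exact Poisson interval. These genes are in no marker list, and the test used the 18326 of 29128 filtered barcodes with at least 1000 UMIs, thinned to that number, before doublet removal and naming.

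The scripts were tested on simulated data. In simulated whole samples the rule called 0% of genes changed 1.5-fold and 100% of those changed 3-fold and 8-fold (27864 genes). Within classes these simulations left out the condition that the class CPM reach that of the whole sample. For T cell-like cells the rule then called 5.97%, 86.6% and 100% (11249 genes) and also 98 unchanged genes, and for erythroid-like cells 0%, 95.5% and 100% (14701 genes). How often the full rule calls such changes within a class was therefore not measured, and few calls there do not show that few genes differ. In 20 simulations without a difference, 0 genes were called for whole samples and for erythroid-like cells. Intervals held the true ratio for 92.0%, 96.0% and 95.5% of 200 genes in the 3 comparisons. A raised matrix list came out at percentile 100 and the others between 3.02 and 88.55. Cells simulated from the profiles of all 17 named classes, 300 each, all came back under their own class. The same rule had named these profiles in these data. This shows only that the scripts recover known profiles, not that the clusters are named rightly. With only 6 classes simulated, the 300 fibroblast-like cells stayed without a name and the others came back right, so naming depends on which classes are present.

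The alternatives covered scaling by the trimmed mean of M values (trims of 30% and 5%), totals without mitochondrial, haemoglobin and ribosomal protein genes or without epd, filters, doublet removal, thinning to 1000 UMIs, clustering resolution, centring within libraries, weights, thresholds of the rule, feature lists and leaving out each library. Software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9. No genome was used, so no coordinates are given.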

Results

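Single cells of the coverings of the adult zebrafish brain were profiled by droplet-based sequencing of polyadenylated RNA, in which each captured transcript is counted once through a unique molecular identifier (UMI). The leptomeninges, the thin inner covering that lies on the brain surface, gave 1 sample made from the linings of 10 female and 10 male fish. The pachymeninges, the outer covering next to the skull, gave 1 sample made from the linings of 12 female and 13 male fish. The leptomeningeal sample was deposited as 4 libraries and the pachymeningeal sample as 6. They are named here by tissue and by the feature list they were counted on, as leptomeningeal libraries A1, A2, C1 and C2 and pachymeningeal libraries A1, A2, B1, B2, C1 and C2. Feature list A held 32523 features with 3 reporters, list B 32524 with 4 and list C 32525 with 5, and list B was used for pachymeningeal libraries alone. The labels do not say how the libraries of a tissue relate to fish or suspensions, so libraries were not treated as replicates and no difference between the tissues has a replicate check. Intervals are 95% intervals and cover counting error only. The labels state about 10000 cells for each tissue. The deposited matrices held 36134 leptomeningeal barcodes with 60160861 UMIs (7059529 to 18736131 UMIs per library) and 13888 pachymeningeal barcodes with 28437537 UMIs (3547004 to 6207765 per library). After filtering, 27036 leptomeningeal and 13246 pachymeningeal cells were kept, with median depths of 1274 and 784 UMIs per cell. Library C2 of the leptomeninges kept 39.4% of its barcodes, because 6708 of 11657 had more than 20% mitochondrial UMIs, and the other 9 libraries kept 91.0% to 98.6%.

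The series title names an anatomical and molecular description of the meninges, and the first comparison was of the cell classes in the 2 layers. Neuron-like cells made up 66.3% (65.7 to 66.8) of kept leptomeningeal cells and 1.89% (1.67 to 2.14) of pachymeningeal cells. Erythroid-like cells, the haemoglobin-bearing cells of the blood, made up 74.4% (73.6 to 75.1) of the pachymeningeal sample and 7.10% (6.80 to 7.41) of the leptomeningeal sample. T cell-like cells were 7.66% (7.21 to 8.12; 1014 cells) in the pachymeninges and 0.766% (0.665 to 0.877; 207 cells) in the leptomeninges. Fibroblast-like cells were 4.27% (3.93 to 4.63) against 0.0703% (0.0423 to 0.110), and epithelial or keratinocyte-like cells 3.13% (2.84 to 3.44) against 0.0111% (0.00229 to 0.0324). B cell-like cells were 1.52% in the pachymeninges and 0.0148% in the leptomeninges, and cells resembling NK or innate lymphoid cells were 0.861% and 0.0370%. Neutrophil-like cells were 0.551% and 0.00740%, and thrombocyte-like cells, the nucleated counterpart of platelets, 0.393% and 0.0999%. The only markers detected in the NK or innate lymphoid-like cluster were gata3, il13 and il4. The list's nkl genes, prf1.1, eomesa, tbx21 and il2rb were not among them, so the name does not show NK cells. Iridophore-like cells, the reflective pigment cells, were 0.732% of pachymeningeal cells and none of 27036 leptomeningeal cells, which allows a share of up to 0.0111% at 3 counts. The leptomeninges held the larger shares of oligodendrocyte or Schwann cell-like cells (4.53% against 0.0755%), radial glia or astroglia-like cells (3.25% against 0.0377%), and macrophage or microglia-like cells (2.03% against 0.415%). The same held for blood endothelial-like cells (0.984% against 0.0151%), mural-like cells (0.248% against 0.00755%) and lymphatic endothelial-type scavenger cells (0.485% against 0.0906%). Leptomeningeal barrier-like cells, which carry ependymin (epd) and keratins, were 0.880% of the leptomeningeal and 0.0604% of the pachymeningeal cells. Their cluster scored 2.95 on the barrier list and 2.54 on the fibroblast list. The split from fibroblast-like cells by score is therefore narrow.

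The class shares differed between libraries of a tissue. Neuron-like cells spanned 21.8% to 78.5% over the leptomeningeal libraries and erythroid-like cells 8.90% to 88.9% over the pachymeningeal libraries, where T cell-like cells spanned 2.33% to 35.7%. Within feature list A, neuron-like cells were 76.4% of leptomeningeal and 3.05% of pachymeningeal cells, and within list C 45.8% and 0.673%. Erythroid-like cells were 7.98% and 81.7% within list A, 5.31% and 87.8% within list C, and 10.7% in the pachymeningeal libraries of list B. T cell-like cells were 0.851% and 3.76% within list A, 0.593% and 2.67% within list C, and 35.4% in list B. Fibroblast-like cells were 0.0663% and 3.02% within list A, 0.0783% and 2.92% within list C, and 12.5% in list B. Macrophage or microglia-like cells were 1.85% and 0.465% within list A and 2.39% and 0.327% within list C. Thrombocyte-like cells turned over, with 0.122% and 0.273% within list A but 0.0559% and 0.0384% within list C, and their pachymeningeal share was 0.243% without library B2. Small shares also rested on single libraries. Without pachymeningeal library A2 the share of radial glia or astroglia-like cells there was 0.0100%, and without B2 and C2 in turn that of blood endothelial-like cells was 0.00811% and 0.00937%. Without B2 no mural-like cell was left in the pachymeninges. Without leptomeningeal library A2 no epithelial or neutrophil-like cell was left in that tissue, and without A1 their shares were 0.0169% and 0.0113%. Named classes held 86.8% of leptomeningeal and 96.1% of pachymeningeal cells. Cluster 3, whose leading genes were mitochondrial and in which 9 neuron markers were detected, stayed without a name and held 11.9% of leptomeningeal and no pachymeningeal cells and made up 67.7% of leptomeningeal library C2. Of the other clusters without a name, cluster 19 held 0.289% of leptomeningeal and 1.28% of pachymeningeal cells, cluster 21 0.692% and 0.400%, cluster 34 0.248% and 0.204%, cluster 24 none and 1.22%, and cluster 40 0.0888% and none. Cluster 31 held no leptomeningeal and 106 pachymeningeal cells. No cluster met the naming rule for the lists of macrophages, dendritic cells, mast cells or eosinophils, ependymal cells, melanophores, xanthophores, osteoblasts, chondrocytes, osteoclasts, skeletal muscle or cycling cells. With at least 500 genes and at most 10% mitochondrial UMIs per cell, pachymeningeal erythroid-like cells were 9.69%, T cell-like cells 27.1% and fibroblast-like cells 12.2%, and macrophage or microglia-like cells became more frequent in the pachymeninges (2.15%) than in the leptomeninges (1.77%). Thinning each cell to 1000 UMIs before clustering, which left out cells with fewer, turned the macrophage or microglia-like shares likewise (3.76% and 2.42%) and lowered the pachymeningeal erythroid-like share to 48.1%. Centring genes within each library left no cluster named fibroblast-like.

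**Figure D1:**
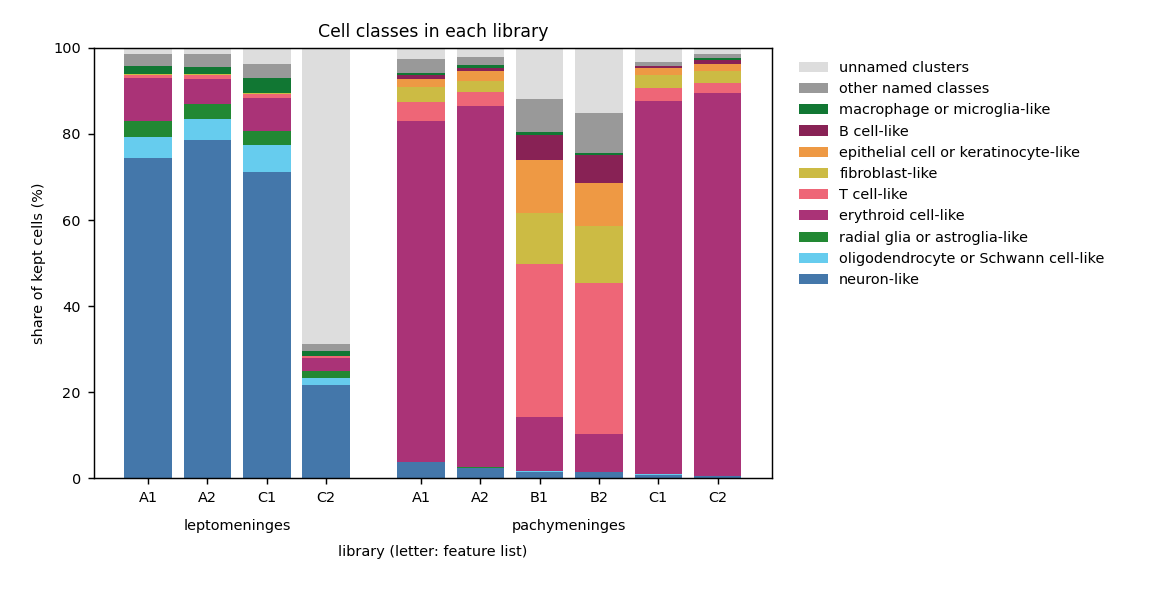
Stacked bars give the share of kept cells (%) in each class for the 4 leptomeningeal and 6 pachymeningeal libraries, with the letter of each name giving the feature list. Neuron-like cells fill 71.1% to 78.5% of leptomeningeal libraries A1, A2 and C1 and 21.8% of C2, and erythroid-like cells fill less of pachymeningeal libraries B1 and B2 (10.7% together) than of the other 4.

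Since neural and erythroid cells made up most of the samples, shares were also taken over the remaining cells. These left out the neuron, oligodendrocyte or Schwann, radial glia and erythroid classes and the mitochondrial cluster 3, and numbered 1879 in the leptomeninges and 3127 in the pachymeninges. Macrophage or microglia-like cells were the most frequent named class of the leptomeninges on this basis, at 29.2% against 1.76% of the pachymeningeal cells. Both clusters of this class were named from the microglia list and none from the macrophage list, so it is not separated here from microglia of the brain. Blood endothelial-like cells followed with 14.2% against 0.0640%, leptomeningeal barrier-like cells with 12.7% against 0.256%, T cell-like cells with 11.0%, and lymphatic endothelial-type scavenger cells with 6.97% against 0.384%. The order differed between libraries, with barrier-like above blood endothelial-like cells in library C1 (12.83% against 10.896%) and T cell-like above barrier-like cells in A2 (13.0% against 12.8%). Scavenger cells were 9.55% and 8.40% in A1 and A2 but 2.91% and 2.55% in C1 and C2, below mural-like cells there (5.81% and 4.59%). In the pooled pachymeninges T cell-like cells led with 32.4%, followed by fibroblast-like cells with 18.1% against 1.01%, epithelial or keratinocyte-like cells with 13.2% against 0.160%, and B cell-like cells with 6.46% against 0.213%. T cell-like cells were 41.6% and 39.1% in pachymeningeal libraries B1 and B2, whereas fibroblast-like cells led them in C1 (24.9% against 24.3%) and C2 (26.3% against 22.2%).

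The next comparison asked which genes were higher in each covering when all kept cells of a tissue were summed. Of 27918 genes tested, 4302 were higher in the leptomeninges and 1215 in the pachymeninges by the rule of size. The rule asked for at least 20 CPM (a gene's UMIs scaled by the total of its tissue), a ratio of at least 2 and no overlap between the libraries of the tissues. Most of the 12 named leptomeningeal genes were highest in neuron-like cells. The gene pou4f2 (ENSDARG00000069737), a POU-domain factor of retinal ganglion cells and other neurons, reached 100.3 CPM against 0.0722 CPM, a fold of 1389 (384 to 11469) from 4405 and 2 UMIs. The neuropeptide gene cart2 (ENSDARG00000045832) reached 572 CPM against 2.71 CPM, 211-fold (168 to 268). The peptide hormone genes pth2 (620-fold, 111 to 24527, against 1 UMI), crhb (390-fold, 152 to 1433) and kiss1 (293-fold, 125 to 903) had their highest class level in neuron-like cells. The transcription factor genes shox (555-fold, 217 to 2039), foxb1a (274-fold, 93.6 to 1331, against 3 UMIs) and barhl2 (221-fold, 107 to 551) peaked there too. The remaining leptomeningeal genes were highest in other classes. The uncoupling protein gene ucp1 (217-fold, 74.1 to 1055, against 3 UMIs) and the engrailed gene en2a (201-fold, 109 to 420) peaked in radial glia-like cells, gabrz (178-fold, 93.8 to 390) in mural-like cells and lhx1a (157-fold, 96.6 to 275) in cluster 21. The mural-like level of gabrz was 90.1 CPM, against 58.0 CPM in the whole leptomeningeal sample. It came from 67 cells with 66578 UMIs of all genes, so this leading class rests on few gabrz UMIs.

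Most of the 12 named pachymeningeal genes were highest in epithelial or keratinocyte-like or in B cell-like cells. The epithelial adhesion gene epcam (ENSDARG00000040534) reached 1476 CPM against 0.501 CPM, a fold of 2947 (1946 to 4704). The claudin genes cldne (3889-fold, 1666 to 11980) and cldnb (1896-fold, 1274 to 2959) and the occludin gene oclnb (2197-fold, 394 to 86834, against 1 UMI) were highest in epithelial or keratinocyte-like cells. The plakophilin gene pkp3a (1665-fold, 845 to 3858), the keratin gene krt97 (1629-fold, 932 to 3153) and icn2 (1198-fold, 880.0 to 1678) were highest there too. The immunoglobulin light chain genes igl3v5 (5384-fold, 966 to 212701, against 1 UMI) and igic1s1 (5129-fold, 1419 to 42361, against 2 UMIs) were highest in B cell-like cells. The defensin-like gene defbl1 was at least 2322-fold higher, from 4391 pachymeningeal UMIs and none in the leptomeninges with a floor of 3 counts over the tissue, and was highest in iridophore-like cells. The genes soul2 (2083-fold, 373 to 82323, against 1 UMI) and f2rl1.2 (1139-fold, 389 to 5527, against 3 UMIs) were highest in clusters 24 and 31. Values of 4 and 6 libraries fall apart without overlap, in either direction, in 0.952% of random orders. Since the rule asks for no overlap, it fixes the direction of these genes within feature lists A and C, and those lists add no check. The median log2 ratio of all genes was 0.57 and moved by -0.51 with trimmed mean of M values scaling and by -0.47 when mitochondrial, haemoglobin and ribosomal protein genes were left out of the total. The leptomeningeal share of the calls, 78.0%, became 64.0% (3478 and 1955 genes) and 65.5% (3836 and 2018 genes) with these scalings. Equal weight per cell class, without the condition on libraries, called fewer genes in each direction and turned some to the opposite tissue. Fewer leptomeningeal genes were also called without the erythroid and neuron clusters, and the counts are given below.

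Gene lists fixed in advance were then compared between the coverings. Antigen presentation genes were higher in the pachymeninges: 10 of 16 measured members met the rule there and none in the leptomeninges, with a median log2 ratio (leptomeninges over pachymeninges) of -2.01. The beta-2-microglobulin gene b2m, part of class I histocompatibility molecules, was at 1566 CPM against 169 CPM (ratio 0.108, 0.105 to 0.111), with b2ml at 0.294, the invariant chain gene cd74b at 0.282 and the class II gene mhc2dab at 0.221. Of 26 measured inflammatory genes 11 were higher in the pachymeninges and none in the leptomeninges, with a median of -2.62. The neutrophil-attracting chemokine gene cxcl8b.1 was at 167 CPM against 1.18 CPM (ratio 0.00709, 0.00529 to 0.00932), and ptgs2a, the inducible prostaglandin synthase, had a ratio of 0.0540, the interferon-induced isg15 of 0.0691 and socs3b of 0.300. These medians lay at percentile 0.01 and below all of 10000 random lists matched on expression.

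Among 17 measured collagens with a single identifier 4 were higher in the pachymeninges, with ratios of 0.344 for the basement membrane gene col4a1, 0.253 for col5a1, 0.216 for col6a1 and 0.0304 for col6a2, and 1 gene, col14a1a, was 16.7-fold (13.4 to 21.0) higher in the leptomeninges. The collagen median was -0.77 (percentile 0.61). The symbol col6a3 has more than 1 identifier and was left out of these counts, and its identifier ENSDARG00000077139 also met the rule in the pachymeninges (29.9 against 5.49 CPM, ratio 0.184, 0.158 to 0.212). None of 27 matrix proteoglycan and glycoprotein genes met the rule, and their median was -0.65 (percentile 0.22). Of 27 junction proteins, cdh2 (4.13-fold), tjp1a (4.34-fold), tjp1b (2.63-fold) and jam3a (16.1-fold) were the most abundant of 6 higher in the leptomeninges. The most abundant of 7 higher in the pachymeninges were cldn7b (ratio 0.00570), dspa (0.0194), cldnh (0.0212) and pkp1b (0.0138), and the median was 0.51 (percentile 24.04). This median changed sign when the erythroid and neuron clusters were left out. Of 32 barrier transporters 6 were higher in the leptomeninges, among them the bicarbonate transporter gene slc4a4a (32.9-fold, 219 against 6.65 CPM), the glucose transporter gene slc2a1a (109-fold, 71.3 to 177, 82.8 against 0.758 CPM), the thyroid hormone transporter gene slco1c1 (8.58-fold) and mfsd2ab (2.22-fold). Another 4 were higher in the pachymeninges, with ratios of 0.248 for slc2a1b, 0.0726 for slc38a5a, 0.00897 for abcb5 and 0.455 for abcc4, and the median was 0.58 (percentile 27.53).

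Retinoid and thyroid hormone genes split 3 to 2 among 23 measured members, with crabp1a (13.5-fold), dio3b (3.33-fold) and dio2 (20.0-fold), which encodes a thyroid hormone deiodinase, higher in the leptomeninges. The genes crabp2a (ratio 0.0235) and rdh10b (0.354) were higher in the pachymeninges, and the median was -0.41 (percentile 0.60). Of 38 secreted growth factor genes bdnf (12.0-fold) and dkk3a (13.4-fold) were higher in the leptomeninges and igfbp5b (0.463), sfrp1a (0.192) and tgfb1a (0.187) in the pachymeninges, with a median of 0.32 (percentile 30.27). Of 33 guidance factors 4 were higher in the leptomeninges, cxcl14 (4.50-fold), cxcl12b (26.5-fold), vegfba (10.6-fold) and vegfab (5.32-fold), with a list median of 0.07 (percentile 5.88). Another 5 were higher in the pachymeninges, among them cxcl12a (0.194), ccl25b (0.0832) and cxcl18b (0.138). Scavenging, lysosome and lipid genes split 3 to 3 of 24, with fabp3 (5.77-fold), lrp1aa (2.38-fold) and lamp1b (3.65-fold) against the cathepsin genes ctsba (0.478), ctsz (0.319) and ctsc (0.386), and a median of 0.24 (percentile 7.57). Immediate early and heat shock genes split 3 to 2 of 24: fosab (4.82-fold, 3947 against 819 CPM), junbb (3.33-fold) and hsp70l (3.56-fold) were higher in the leptomeninges. In the pachymeninges fosl1a (0.320) and dusp1 (0.172) were higher, with a list median of 0.02 (percentile 2.98) that changed sign when the erythroid and neuron clusters were left out. Of 19 replication and cell cycle genes hmgb2a (0.402) was higher in the pachymeninges and none in the leptomeninges, with a median of -0.58 (percentile 2.40). Ratios also moved with the feature list, and 56 of the 80 list members that met the rule had a ratio within list A or C over 1.5 times from the pooled one. Within lists A and C the ratios of crabp1a were 152 and 160, of dio2 71.8 and 203, of dio3b 2.73 and 12.1 and of slc2a1a 1031 and 39.0. Within feature lists A and C the medians of the cell cycle list were 0.15 and 0.41 and of the retinoid list 0.13 and 0.0298, opposite in sign to the pooled values. Those of the antigen list were -1.29 and -1.75, of the inflammatory list -1.32 and -1.68, of the collagens -0.30 and -0.16 and of the matrix list -0.06 and -0.15. The trimmed mean of M values scaling moves all genes alike, and with it the medians that lay slightly above 0 came to lie below it, at -0.27 for scavenging, -0.19 for growth factors, -0.44 for guidance and -0.49 for immediate early genes.

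The levels of list members were then compared across classes. Because epd took 59.4% of the UMIs of barrier-like cells, the CPM of other genes there is low, and with epd left out of the totals 6 of 267 members had another leading class. Barrier-like cells then led 12 members in place of 7, with col12a1a, bgnb, igf2b, igfbp2a and lrp1aa added. Among 16 collagens counted, 8 were highest in pachymeningeal fibroblast-like cells (col5a1 303 CPM, col6a2 272 CPM, col6a1 253 CPM), while the basement membrane collagens col4a1 (811 CPM) and col4a2 (571 CPM) peaked in leptomeningeal mural-like cells and col18a1a (335 CPM) in barrier-like cells. Pachymeningeal fibroblast-like cells also led 7 of 19 matrix genes, mural-like cells led 5, among them sparc (706 CPM) and the laminin genes lama4 (601 CPM) and lamc1 (466 CPM), and the fibronectin gene fn1b peaked at 4675 CPM in thrombocyte-like cells. Blood endothelial-like cells led 10 of 31 barrier transporters, with slc2a1a at 6309 CPM, slc7a5 at 1932 CPM and slco1d1 at 1115 CPM, and radial glia-like cells led 4, with slc4a4a at 3155 CPM. Epithelial or keratinocyte-like cells led 9 of 24 junction genes, among them cldn7b (1377 CPM) and the desmoplakin gene dspa (903 CPM), and cldn5a, a tight junction gene of brain endothelium, reached 1635 CPM in blood endothelial-like cells. The retinol carrier gene rbp4 was at 13711 CPM in barrier-like cells, or 33798 CPM without epd in the total, and at 12480.5 CPM in fibroblast-like cells. The retinoic acid synthesis gene aldh1a2 peaked in cluster 34 (1315 CPM) and dio2 in radial glia-like cells (1307 CPM). Among guidance factors, cxcl12a (6420 CPM), ccl25b (5600 CPM) and cxcl18b (2829 CPM) peaked in pachymeningeal fibroblast-like cells and cxcl12b (2203 CPM) in blood endothelial-like cells. T cell-like cells of the pachymeninges led 5 of 15 antigen presentation genes (b2m 5547 CPM) and macrophage or microglia-like cells led 3 in each tissue, with the class II invariant chain gene cd74a at 21468 CPM in the leptomeninges. Inflammatory genes were led by fibroblast-like cells for cxcl8b.1 (1244 CPM), blood endothelial-like cells for socs3a (3393 CPM), B cell-like cells for ccl35.1 (2544 CPM) and neutrophil-like cells for il1b (2303 CPM). Lymphatic endothelial-type scavenger cells led 5 of 20 lysosome and lipid genes, with the cathepsin gene ctsla at 20249 CPM and lgmn at 1383 CPM, while fabp3 peaked in mural-like cells (2719 CPM). Of 24 immediate early and heat shock genes, mural-like cells led 6 (fosab 9478 CPM) and blood endothelial-like cells 5 (fosb 11232 CPM), and hsp70.3 peaked in iridophore-like cells (7017 CPM). Secreted growth factors were spread out, with igfbp5b (2232 CPM) in cluster 34, igfbp1a (1783 CPM) in pachymeningeal erythroid-like cells, bdnf (651 CPM) in pachymeningeal neuron-like cells and sfrp1a (501 CPM) in fibroblast-like cells. Cluster 21 led 12 of 16 replication genes, among them stmn1a (311 CPM), pcna (170.0 CPM) and mcm7 (83.5 CPM).

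**Figure D2:**
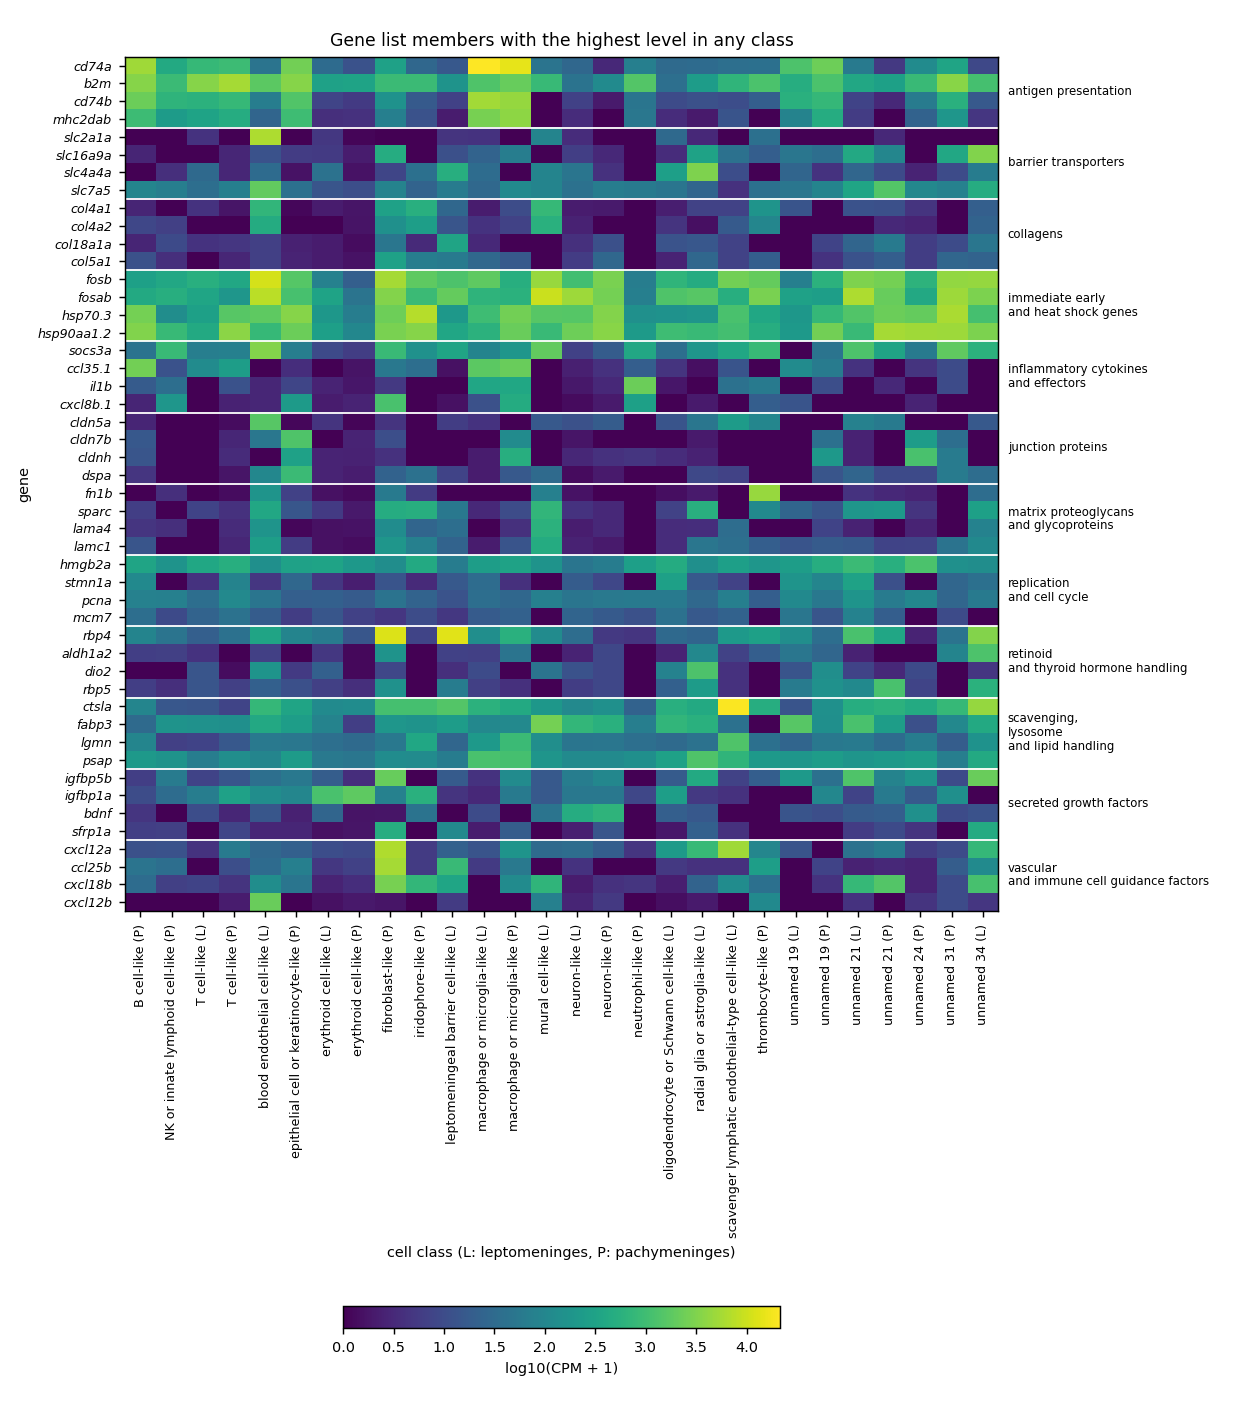
The heat map shows log10(CPM + 1) of the 4 members of each gene list with the highest level in any class (vertical axis), in each class with at least 50 cells in a tissue (horizontal axis; L, leptomeninges and P, pachymeninges). The bright cells include cd74a in leptomeningeal macrophage or microglia-like cells (21468 CPM), ctsla in lymphatic endothelial-type scavenger cells (20249 CPM) and rbp4 in barrier-like (13711 CPM, with epd in the total) and fibroblast-like cells (12480.5 CPM).

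T cell-like cells, all of cluster 10, were compared between the coverings as the same class in 2 places. The top 10 genes of this cluster held 1 marker of the T cell list (sla2) and 1 of the NK or innate lymphoid list (il2rb). Its defining gene prf1.1 is on the latter list too. The cluster may therefore mix cell types, and whether their mix differed between the tissues was not tested. In the 1014 pachymeningeal cells the chemokine gene ccl20a.3 (ENSDARG00000101040) was at 675 CPM, 208-fold (37.3 to 8222) above the leptomeninges, where 1 UMI was counted against 1722. The autophagy gene vmp1 (805 against 13.0 CPM, 62.0-fold, 24.2 to 228), the aryl hydrocarbon receptor target cyp1a (841 against 19.5 CPM, 43.2-fold, 19.8 to 118) and the filamin gene flna (771 against 22.7 CPM, 33.9-fold, 16.4 to 84.5) were also higher in the pachymeninges. So were stmn1a (26.8-fold, 4.76 to 1064), the interferon-related gene helz2 (23.6-fold, 4.18 to 935), ifngr1l (23.3-fold, 4.14 to 926), which resembles interferon gamma receptors, and ponzr6 (22.5-fold, 3.98 to 892), each against 1 leptomeningeal UMI. In the 207 leptomeningeal cells the highest fold was that of the transcriptional repressor gene hic1 (ENSDARG00000055493), at 48.7 against 1.96 CPM, 24.8-fold (8.58 to 87.3) from 15 and 5 UMIs. It was followed by the ephrin gene efna2a (16.6-fold, 7.06 to 41.8), the polycomb gene bmi1b (14.5-fold, 6.81 to 32.3) and the amino acid transporter gene slc6a15 (14.3-fold, 6.47 to 33.3). Next came arhgap12b (13.8-fold, 6.99 to 28.1), ramp2 (11.6-fold, 4.79 to 29.2), fam84b (10.8-fold, 4.36 to 27.4) and tsc1a (9.46-fold, 2.997 to 30.6). None of these had more than 25 UMIs in the leptomeningeal cells. Several named genes differed likewise between the whole samples. There cyp1a was at 4.896 CPM in the leptomeninges and 212 CPM in the pachymeninges, and flna at 20.27 and 133.8 CPM. The gene bmi1b was at 36.32 and 4.587 CPM and arhgap12b at 49.55 and 5.418 CPM. Of the named genes, vmp1, stmn1a, ifngr1l and ramp2 leaned the other way there. Whether the folds belong to T cell-like cells or to the whole tissue or suspension was not tested. Feature list B, which has no leptomeningeal library, held 641 of the 1014 pachymeningeal cells, so the pooled folds rest largely on unmatched libraries. Within list A the folds were 13.6 for hic1, 6.80 for efna2a, 17.0 for bmi1b and 6.04 for slc6a15. They were 14.7 for arhgap12b and for ramp2, 10.2 for fam84b and 15.9 for tsc1a.

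By the rule of size 125 genes were higher in leptomeningeal and 458 in pachymeningeal T cell-like cells, of 11192 tested, from 308043 and 2549910 UMIs. Immediate early and heat shock genes included klf2a, a factor of resting lymphocytes, higher in the leptomeninges (6.79-fold, 4.12 to 11.12), and hsp70.3 (ratio 0.177, 0.142 to 0.218), hsp90aa1.2 (0.114, 0.0953 to 0.135) and dusp1 (0.468, 0.388 to 0.561) higher in the pachymeninges. The other 20 of 24 measured members did not meet the rule, and the list median was -0.50 (percentile 5.25). The ribonucleotide reductase gene rrm1, with 95 pachymeningeal UMIs and none in the leptomeninges, and stmn1a were the replication genes higher in the pachymeninges, 2 of 16 with a median of -0.66 at percentile 2.34. Of 16 antigen presentation genes psmb13a (0.307) met the rule (median -0.61, percentile 5.36), of 16 scavenging genes plin2 (0.214; median -0.39, percentile 11.28), and of 14 barrier transporters abcc1 (0.419), abcc4 (0.373) and slc7a5 (0.484), all higher in the pachymeninges (median -0.12, percentile 51.84). No member of the inflammatory list (median -0.50 over 15), the collagens (-0.27 over 3), the matrix list (0.26 over 4), the junction list (0.25 over 6), the retinoid list (0.56 over 3), the growth factors (0.55 over 5) or the guidance factors (-0.07 over 6) met it. Neuron markers in the leptomeningeal T cell-like cells stood at a median of 10.2% of their level in the whole leptomeningeal sample. The median depths were 1388 UMIs per cell in the leptomeninges and 2050 in the pachymeninges. Library C2 of the leptomeninges had fewer than 20 such cells and did not enter the library range, and genes without overlap between 3 and 6 libraries come by chance in 2.38% of orders in either direction. Simulations without any difference called 17 to 39 leptomeningeal and 38 to 52 pachymeningeal genes. The all-gene median of -0.12 moved by -0.20 with the trimmed mean of M values, which gave 87 and 601 genes. It moved by 0.22 without mitochondrial, haemoglobin and ribosomal protein genes in the total, where the leptomeningeal share of the calls rose from 21.4% to 39.9% (244 and 367 genes). Without leptomeningeal libraries A1, A2 and C1 in turn the leptomeningeal count was 197, 230 and 209. Within feature list A the counts were 275 and 1069, list C had too few leptomeningeal cells, and stmn1a had a ratio of 0.605 there.

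**Figure D3:**
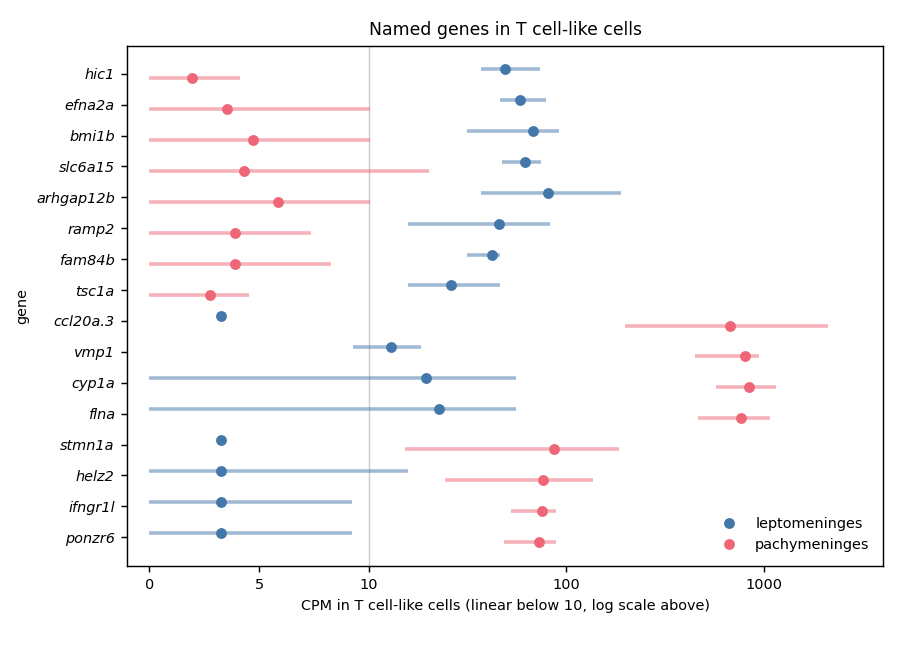
Points give the CPM of the 16 named genes in T cell-like cells of the leptomeninges and the pachymeninges, on an axis that is linear below 10 and logarithmic above, and lines span the lowest to the highest library among those with at least 20 such cells. The lines of the tissues do not overlap for any gene, as the rule of size asks, and those of ccl20a.3 and stmn1a in the leptomeninges have no length because their single UMI lies in a library with fewer such cells.

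In erythroid-like cells few genes met the same rule over the pooled libraries. Of 14639 genes tested, 3 were higher in the pachymeninges: nubp1, which encodes an iron-sulfur cluster assembly protein (33.6 against 14.8 CPM, 2.28-fold, 1.53 to 3.53), the kinase gene wnk4b (360 against 158 CPM, 2.27-fold, 2.01 to 2.57) and the phosphodiesterase gene PDE3B (143 against 71.0 CPM, 2.01-fold, 1.67 to 2.43). The 3 genes higher in the leptomeninges lay outside the naming rule and were chosen after their values were seen: the mitochondrial genes mt-nd3 (9.61-fold, 9.03 to 10.2) and mt-co1 (5.27-fold, 5.14 to 5.41) and zgc:158689 (117-fold, 47.9 to 369, from 80 and 5 UMIs). No member of any of the 12 gene lists met the rule. The list medians were 1.49 for immediate early and heat shock genes (percentile 100), 1.69 for growth factors (99.95), 1.61 for retinoid genes (99.92), 1.45 for junction proteins (99.84), 1.13 for matrix genes (84.66) and 0.70 for collagens (93.61). They were 0.49 for inflammatory genes, 0.45 for cell cycle genes, 0.40 for transporters, 0.16 for antigen presentation, 0.11 for scavenging and -0.46 for guidance factors (0.79). The members with high leptomeningeal values lay below their whole-tissue level, where the rule calls no gene, as for fosab with 324 CPM in leptomeningeal erythroid-like cells, 45.7 CPM in pachymeningeal ones and 3947 CPM in the whole leptomeningeal sample. Neuron markers in leptomeningeal erythroid-like cells were lower than in neuron-like cells by a median ratio of 9.94. Different clusters held the class in the 2 tissues, with clusters 0 (53.5%) and 1 (44.5%) in the pachymeninges and cluster 9 (87.7%) in the leptomeninges. The counts rose to 35 and 49 genes within feature list A and to 70 and 44 within list C, which shared 1 and none with the 3 and 3 pooled genes. They were 3 and 30 with equal weight per library and 4 and 44 with each cell thinned to 1000 UMIs. Within feature list A the ratios of nubp1, wnk4b and PDE3B (leptomeninges over pachymeninges) were 0.387, 0.342 and 0.417, within list C 0.635, 0.726 and 0.679, and those of mt-nd3 and mt-co1 were 8.28 and 4.35 within list A and 14.6 and 8.35 within list C. The equal split of the calls became 9.38% leptomeningeal (3 and 29 genes) with the trimmed mean of M values, which moved the all-gene median of 0.25 by -0.52, and 25.0% (1 and 3 genes) without epd in the total. Leaving out single libraries gave counts between 1 and 10 for the leptomeninges and 3 and 13 for the pachymeninges. They were 10 and 9 without leptomeningeal library C2, 6 and 13 without C1, 1 and 6 without A2 and 6 and 8 without A1. Among pachymeningeal libraries they were 5 and 6 without B2, with pachymeningeal counts of 7, 6 and 8 without A1, C1 and C2.

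Ependymin and the reporters listed among the features were examined last. In leptomeningeal barrier-like cells epd made up 59.4% (59.4 to 59.5) of all UMIs, 1021666 of 1718980, at a median depth of 5041.5 UMIs per cell. It was 0.143% of UMIs in leptomeningeal T cell-like cells, a class that should lack it, where 78.7% of cells held an epd UMI at a median depth of 1388 UMIs. It was 0.00369% in pachymeningeal T cell-like cells, where 8.38% of cells held it at 2050 UMIs. Lymphatic endothelial-type scavenger cells of the leptomeninges held 1.98% epd UMIs, although 74.0% of cells held one at a median depth of 2247 UMIs, no more than among T cell-like cells. Pachymeningeal fibroblast-like cells held 0.00345%. The reporter lyv1_dsred2 was counted in 15.3% of lymphatic endothelial-type scavenger cells of the leptomeninges at a median of 2247 UMIs and in 0.0167% of neuron-like cells at 1441 UMIs. In all, 49 of its 52 UMIs lay in the scavenger cells, all in libraries A1 (36) and A2 (16). The reporter GFPd2 was at 480 CPM in these scavenger cells (20.6% of cells) and 451 CPM in barrier-like cells (25.6% of cells at 5041.5 UMIs), or 489 and 1113 CPM without epd in the totals, against 4.95 CPM in leptomeningeal neuron-like cells (0.681% of cells at 1441 UMIs).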

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

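The test of brain tissue for the neuron-like cells was chosen only after its result was seen, and the test of free RNA for them was added after all other results, before its own was seen. The other tests below were fixed before their results were seen.

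Over 11 sets of library values, 2 had a library far from the others, both in leptomeningeal library C2, and chance alone marks about 1 set in 20. This library kept 39.4% of its barcodes, against 91.0% to 93.4% in the other 3 leptomeningeal libraries, and neuron-like cells were 21.8% of its kept cells, against 71.1% to 78.5%. Its median share of mitochondrial UMIs was 22.1%, against at most 6.53% in the other libraries, and the mitochondrial cluster 3 held 67.7% of its kept cells.

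Reporters lie outside the comparisons of genes, and their UMIs exceeded what a count of 0 allows. GFPd2 had 1212 UMIs in leptomeningeal and 85 in pachymeningeal cells. The reporter epd_ribo had 1056 UMIs in leptomeningeal and 2276 in pachymeningeal cells, at 229 CPM in pachymeningeal NK or innate lymphoid-like cells, 205 CPM in pachymeningeal T cell-like cells, 157 CPM in pachymeningeal fibroblast-like cells and 193 CPM in leptomeningeal barrier-like cells (476 CPM without epd in the total), against 10.8 CPM in leptomeningeal neuron-like cells. With epd in the totals, cluster 19 had the highest levels, 259 CPM in the leptomeninges and 243 CPM in the pachymeninges. Pachymeningeal B cell-like cells had 225 CPM. A UMI of epd_ribo was held by 32.3% of pachymeningeal T cell-like cells at a median of 2050 UMIs and by 1.76% of leptomeningeal neuron-like cells at 1441 UMIs. Its level per library ran from 22.7 to 201 CPM in the pachymeninges and from 17.4 to 46.2 CPM in the leptomeninges. The reporter lyv1_dsred2 had 52 UMIs, all leptomeningeal. The reporter mCardinal, listed for the libraries of list C, had 505 leptomeningeal UMIs, at 51.1 CPM in oligodendrocyte or Schwann-like cells, 41.9 CPM in cluster 3, 41.7 CPM in neuron-like cells and 36.3 CPM in radial glia-like cells. It had 37 pachymeningeal UMIs, 12 of them in cluster 24 at 82.1 CPM. The reporter mCherry had 8 leptomeningeal UMIs, all in library C1, and 3 in the pachymeninges.

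Most kept leptomeningeal cells were neuron-like, although the tissue is a covering of the brain. A single pool of free RNA is argued against as the whole source of the neuronal RNA in libraries A1, A2 and C1, since barcodes with both a GABA and a glutamate gene were 0.373 (0.347 to 0.400) times as many as independence gives over all 4 libraries and 0.316 to 0.363 times in each of these 3. In library C2 the ratio was 0.727 (0.6249 to 0.842), so free RNA stays open there. Brain tissue carried along with the lining remains open and may account for the neuron-like cells: cells of the radial glia and oligodendrocyte classes were present in every leptomeningeal library, at 3.14% of kept cells in library C2 and 8.46% to 9.66% in the others. Neurons that belong to the leptomeninges were not tested and stay open too.

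Pachymeningeal libraries B1 and B2 held few erythroid-like cells (10.7% together, against 84.5% in the other 4). A difference in depth is argued against for cells with at least 1000 UMIs. In these, thinned to 1000 UMIs (1313 and 3791 cells), the shares were 1.60% and 64.2%, a ratio of 40.1. Cells with fewer UMIs were left out, and 2429 of 9853 pachymeningeal erythroid-like cells reached that depth. The thinned shares rest on 21 and 2434 erythroid-like cells, so the size of the ratio does not carry over to all cells. Removal of erythroid cells alone cannot be told apart from other differences: among the remaining cells 2 of the 6 leading classes lay outside the range of the other libraries, T cell-like cells with 40.3% (37.9 to 42.8) against 22.2% to 25.7% and fibroblast-like cells with 14.2% (12.5 to 16.0) against 18.8% to 26.3%, and 4 lay inside. Libraries B1 and B2 are also the only ones counted on feature list B, and the labels name no difference between the libraries of a tissue, so no biological explanation was tested.

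T cell-like cells differed between the coverings, and counting error of few cells is argued against as the whole cause, since 125 and 458 genes were higher in the leptomeninges and the pachymeninges, against at most 39 and 52 in simulations with no difference, which leave out variation between cells. Depth per cell is argued against for the pachymeningeal genes, since 448 genes were higher in the pachymeninges with each cell thinned to 1000 UMIs (156 of 207 and 883 of 1014 cells deep enough), 263 of them among the 458. For the leptomeningeal genes it stays open in part, since 91 were called in the thinned cells and 44 of them were among the 125. Free RNA diluting the leptomeningeal cells is argued against as far as it has the composition of the whole sample, since neuron markers there stood at a median of 10.2% of the whole-sample level. A difference between the tissues, such as in the state of their T cells or in the mix of cells within the cluster, may be a cause. A difference in handling between the suspensions may be one too, and neither was tested.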

How the results depend on the processing

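The alternatives that count mitochondrial ribosomal and transfer RNA in the filter, use only the libraries of feature list A or of list C, leave out the list B libraries, leave out the erythroid and neuron clusters, or leave epd out of the total were chosen only after the data were seen. Over all results and alternatives, 926 values stayed within the spread used (within 1.5 times for counts), 271 moved beyond it and 11 changed direction, counted for list medians only where the median lay in the outer 2.5% of random lists at either end. The cause was not tested for any change below, except that a stricter or looser rule of size calls fewer or more genes by construction. No paired analysis was possible because each tissue has 1 sample, so that only 1 replicate number is shared. The comparisons within T cell-like and erythroid-like cells gave no value under the stricter cell filter, and that within T cell-like cells none after centring or within list C alone. The T cell-like comparison rests on 308043 leptomeningeal UMIs, which limits its precision.

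Gene counts follow as leptomeninges and pachymeninges, against 4302 and 1215 for whole samples, 125 and 458 for T cell-like and 3 and 3 for erythroid-like cells. Without mitochondrial, haemoglobin and ribosomal protein genes in the total, pachymeningeal genes of whole samples numbered 2018 (1213 of them called before), leptomeningeal genes of T cell-like cells 244 (125 called before) and erythroid-like genes 25 and 28, and the scavenging median was -0.23. Trimmed mean of M values scaling gave 1955 pachymeningeal genes (1213 called before), 29 pachymeningeal erythroid-like genes and a scavenging median of -0.27. At 100 CPM or more there were 1035 and 352 genes of whole samples and 32 and 194 of T cell-like cells. A ratio of at least 4 gave 2797 and 784, 52 and 177, and 0 pachymeningeal erythroid-like genes. Without a minimum CPM there were 8604 and 2946 genes and 12 and 28 erythroid-like genes. Without the condition on libraries there were 295 and 1001 T cell-like and 15 and 18 erythroid-like genes. Equal weight per cell class without that condition gave 1148 and 823 genes, 828 and 225 of them called before, while 64 of the leptomeningeal and 13 of the pachymeningeal genes called before were called in the opposite tissue.

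With at least 500 genes and at most 10% mitochondrial UMIs, 1844 pachymeningeal genes were called (1144 before), the antigen median was -2.63 and the immediate early median -0.57. The pachymeningeal shares there were 27.1% T cell-like, 9.69% erythroid-like and 12.2% fibroblast-like, the leptomeningeal shares 77.2% neuron-like and 6.16% oligodendrocyte or Schwann-like, and macrophage or microglia-like cells turned to 1.77% and 2.15%. Thinning to 1000 UMIs before clustering (16752 and 5104 cells) gave 15.4% T cell-like, 48.1% erythroid-like and 7.05% fibroblast-like cells in the pachymeninges, 72.9% neuron-like and 5.12% oligodendrocyte or Schwann-like cells in the leptomeninges, and macrophage or microglia-like cells turned to 2.42% and 3.76%. Thinning each cell after clustering gave 44 pachymeningeal erythroid-like genes. Centring within libraries gave 56.4% erythroid-like and 0% fibroblast-like cells in the pachymeninges and 3.44% oligodendrocyte or Schwann-like cells. Double the resolution gave 951 pachymeningeal T cell-like genes (393 called before), 6.71% T cell-like and 1.89% fibroblast-like cells in the pachymeninges and 3.44% oligodendrocyte or Schwann-like cells. With the gene lists among the variable genes there were 5 pachymeningeal erythroid-like genes and 3.75% oligodendrocyte or Schwann-like cells. Equal weight per library gave 30 pachymeningeal erythroid-like genes, 13.9% T cell-like, 60.03% erythroid-like and 6.14% fibroblast-like cells in the pachymeninges and 61.5% neuron-like cells. Mitochondrial ribosomal and transfer RNA in the filter gave 9 and 9 erythroid-like genes, 72.6% neuron-like and 5.25% oligodendrocyte or Schwann-like cells. Without any filter there were 1 and 6 erythroid-like genes, 54.2% neuron-like and 3.05% oligodendrocyte or Schwann-like cells, and without doublet removal 65.2% neuron-like cells.

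Within list A there were 275 and 1069 T cell-like genes (86 and 365 called before) and 35 and 49 erythroid-like genes. The medians were -1.29 for antigen presentation, -1.32 for inflammatory genes and, changing direction, 0.15 for cell cycle and 0.13 for retinoid genes. The shares within list A were 3.76% T cell-like, 81.7% erythroid-like and 3.02% fibroblast-like in the pachymeninges and 76.4% neuron-like and 4.88% oligodendrocyte or Schwann-like in the leptomeninges. Within list C there were 70 and 44 erythroid-like genes, medians of 1.40 for transporters, -1.68 for inflammatory genes and, changing direction, 0.41 for cell cycle and 0.0298 for retinoid genes. That list had pachymeningeal shares of 2.67% T cell-like, 87.8% erythroid-like and 2.92% fibroblast-like cells, leptomeningeal shares of 45.8% neuron-like and 3.83% oligodendrocyte or Schwann-like cells, and thrombocyte-like shares that turned to 0.0559% and 0.0384%. Without the list B libraries there were 8 and 8 erythroid-like genes, an inflammatory median of -1.42, and a cell cycle median that turned to 0.0290. Shares there were 3.26% T cell-like, 84.5% erythroid-like and 2.97% fibroblast-like cells in the pachymeninges. Without erythroid and neuron clusters there were 2244 leptomeningeal genes (1897 called before), and the medians were -0.70 for immediate early, -0.33 for junction and 0.69 for scavenging genes.

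Leaving out each library in turn gave 4219 to 4507 and 1098 to 1316 genes for whole samples, 129 to 230 and 463 to 665 for T cell-like cells and 1 to 10 and 3 to 13 for erythroid-like cells. The T cell-like count for the leptomeninges was 197, 230 and 209 without leptomeningeal libraries A1, A2 and C1. The erythroid-like counts were 10 and 9 without leptomeningeal library C2, 6 and 13 without C1, 1 and 6 without A2, 6 and 8 without A1 and 5 and 6 without pachymeningeal library B2, and the pachymeningeal count was 7, 6 and 8 without pachymeningeal libraries A1, C1 and C2. Over these settings neuron-like cells were 60.3% to 75.4% and oligodendrocyte or Schwann-like cells 4.20% to 5.15% in the leptomeninges, and T cell-like cells 5.61% to 9.10%, erythroid-like cells 70.9% to 79.2% and fibroblast-like cells 3.61% to 4.84% in the pachymeninges. List medians ran from -2.19 to -1.85 for antigen presentation, -2.90 to -2.03 for inflammatory genes, -0.90 to -0.53 for collagens, -0.86 to -0.31 for matrix genes, -0.77 to -0.23 for cell cycle and -0.61 to -0.20 for retinoid genes. They ran from -0.08 to 0.23 for immediate early genes, -0.07 to 0.34 for guidance factors, 0.13 to 0.45 for growth factors, 0.19 to 0.32 for scavenging, 0.38 to 0.70 for junction proteins and 0.40 to 0.65 for transporters. Medians spread more over the 24 pairs of 1 library of each tissue. Only antigen presentation (-2.87 to -1.11) and inflammatory genes (-3.65 to -1.17) kept their sign there. Every other list crossed 0, among them collagens (-2.09 to 0.36), matrix (-1.85 to 0.40), retinoid (-1.54 to 1.39) and cell cycle genes (-1.86 to 0.73).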

Other observations

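The comparison of barrier-like with fibroblast-like cells and the description of the clusters without a name were chosen only after the data were seen. Barrier-like cells of the leptomeninges (238 cells) and fibroblast-like cells of the pachymeninges (566 cells) were compared with epd left out of the totals. These are differently named classes in different tissues, so each ratio joins both differences. The names are not sharply apart. The barrier-like cluster scored 2.95 on the barrier and 2.54 on the fibroblast list, and only epd, krt18a.1 and krt8 were detected of its list. The fibroblast-like cluster scored 5.99 on the fibroblast list and 4.67 on the barrier list, above the barrier-like cluster itself. By intervals beyond 2-fold, barrier-like cells were higher in 5 of 17 barrier transporters and fibroblast-like cells in 6. Those higher in barrier-like cells were slc4a4a by 183-fold (115 to 310), slc16a12b by 488-fold (134 to 4053, against 2 UMIs), slc12a2 by 7.37-fold, and slc47a1 and slc22a6l by 903-fold and 817-fold, each against 1 UMI. Barrier-like cells were also higher in col18a1a, the source of endostatin (16.6-fold, 13.7 to 20.3), the proteoglycan gene bgnb (9.08-fold), the lipid transfer gene pltp (29.3-fold), ccbe1, a factor of lymphatic growth (16.4-fold), the cathepsin gene ctsla (3.26-fold), fabp3 (3.30-fold) and rbp4 (2.71-fold). Fibroblast-like cells were higher in the chemokine gene cxcl12a (barrier over fibroblast ratio 0.00804, 51.6 against 6420 CPM), ccl25b (0.385), col6a1 (0.0113), tnc (0.0294), sparc (0.272), the cadherin gene cdh11 (0.0225), igfbp5b (0.0193), aldh1a2 (0.0872) and cd74a (0.120). On the same basis fibroblast-like cells led 12 of 17 matrix genes against 2, 7 of 15 collagens (with 2 identifiers of col6a3 counted apart) against 2, 10 of 17 growth factors against 1, 11 of 20 guidance factors against 3 and 8 of 10 inflammatory genes against none. Barrier-like cells led 4 of 18 scavenging genes against 1.

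Several clusters without a name carried the genes of recognisable tissues next to the brain. Cluster 19 was led by the pituitary hormone genes pomca, cga, lhb, tshba and gh1, and cluster 21 by photoreceptor and pineal genes such as rcvrnb, exorh, gnat1 and asmt. Cluster 24, found in the pachymeninges alone, was led by odorant and vomeronasal receptor genes such as or132-2 and v2rl1, and 7 markers of ciliated ependymal cells were detected in it. Cluster 31, also pachymeningeal, was led by rgs5a, capga, kitlgb and scgn. Cluster 34, present in both layers, was led by slc47a2.1, slc16a5b, pvalb8, csf1a and rh50, and epd, krt18a.1 and krt8 were detected in it. Over the libraries epd was 1.64% to 3.21% of UMIs in the leptomeninges and 0.00294% to 2.72% in the pachymeninges, the highest in pachymeningeal library B1. That library had 105250 epd UMIs and 3 barrier-like cells, and 16.96% of its cells held an epd UMI. Its share therefore does not describe most of its cells. Pachymeningeal libraries B2 and C2, with no barrier-like cell, had 140 and 119 epd UMIs.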
